A study of Danio rerio with 6 samples.

How the data were processed

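Gene expression was measured in olfactory rosettes, the paired nasal organs that carry the sensory epithelium, dissected from adult zebrafish (Danio rerio) of 1 to 2 years and mixed sex. Per the labels, 3 samples came from wild-type siblings and 3 from fish homozygous for a mutation in rag1, the gene whose product starts the recombination of antigen receptor genes. RNA was labelled by in vitro transcription and hybridised to 6 arrays in 1 colour, 1 array per sample. Nothing in the labels says how many fish gave a sample or that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical. For mutant replicate 2 a source field reads wild type, while its title and its strain field both give the mutant, and it was kept with the mutants. Arrays are named by group and number. Only the number 2 is spelled out in the titles of both groups, and the other numbers only name samples in the order in which they were listed.

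The deposited scanner tables hold 1 raw intensity per spot and a local background, each with its standard deviation, and record neither background subtraction nor normalization, per the file headers. The scanner and the software that measured the spots are not given in the sources used here. Each array has 19200 spots, among them 2707 blank spots, 36 control spots with bacterial names and 172 spots of 1 beta-actin control. A damaged line in the table of mutant replicate 1 left 1 spot unreadable, and that spot was left out on all 6 arrays. The values show the brightness to be summed over the spot: it has a ceiling of 6553500, which is 100 times 65535, the ceiling of a pixel. It was divided by 100 so that the offset applied on the scale of a pixel.

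The authors' deposited value table holds a ratio per probe and sample, and the values alone show how it is centred: every probe's median over the 6 arrays lies within 0.00025 of 1. The column medians were 1.03, 1.00 and 0.955 for wild-type replicates 1 to 3 and 1.02, 0.990 and 0.994 for mutant replicates 1 to 3. On the log2 scale each column had a correlation across probes of 0.963 to 0.979 with the centred scanner values of its own array and of at most 0.471 with those of any other array, which sets its direction and bears out the match of its spot numbers. How the authors scaled each array before centring, and whether they subtracted a background, stays unknown. This table was used only as an alternative.

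A print block of the array was misread on 1 array. The spots lie in 48 blocks, and each block on each array was set against the median of the other arrays, at its own position and 1 row of spots away. In 1 block of wild-type replicate 2 the correlation was 0.241 at its own position and 0.981 at 1 row on, while all other of the 288 pairs of block and array had at least 0.945 at their own position and at most 0.291 at 1 row off. The authors' table carries the same shift (r = 0.998 with the scanner values over 342 probes of the block). The 400 spots of this block were left out on all arrays. This was decided after a first count of changed probes had been seen (604 with the block, 747 without it), and the values with the block kept are among the alternatives.

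Background was corrected with normexp in limma 3.58.1 (R 4.3.3) with an offset of 50, arrays were quantile normalized, the beta-actin spots were averaged and the other control spots dropped, which left 15885 probes. The filter planned on the local background was passed by 100% of the blank spots on every array and separated nothing, so a probe was kept when it exceeded the 95th percentile of the array's blank spots on all 3 arrays of at least 1 group, the last of the filters planned. It kept 15611 probes, and 15160 probes were above the blank spots on all 6 arrays. The scale of the offset was also set after the values had been looked at. Median brightness of the gene spots was 4.84 to 7.37 times that of the blank spots, 96.3% to 99.53% of probes lay above the blank spots, and 22 to 38 probes per array were saturated. The number of arrays limits the precision. The 172 actin spots had an SD of 0.281 to 0.517 (log2) within an array.

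Probe names came from the platform annotation, updated through gene identifiers to the current symbols of assembly GRCz12tu, which changed 1 symbol. Of the probes, 1 symbol was found for 5773, several for 73 and none for 10037, and 2 probes whose accession disagreed between sources stayed unnamed. The 5773 probes carry 5239 symbols. A probe without a symbol is unnamed here, not without a gene. Where a gene had several probes, the brightest stood for it in tests of gene lists, which left 5171 genes, and probes of a named gene that disagree are given together. A probe of a gene family may also detect its close relatives, which was not tested.

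Mutant and wild-type arrays were compared per probe with lmFit and eBayes of limma, 2-sided, with Benjamini-Hochberg adjustment over the 15611 probes and a threshold of 0.05. Differences are log2, mutant minus wild type, with standard errors from the moderated fit and 7.52 degrees of freedom. On simulated values with the spread of these arrays, this comparison recovered 47% of 100 probes changed by 2-fold and 87% of 100 changed by 4-fold among 15611 probes, and 4.96% of its calls were false. The changed probes were drawn from spots well above the blank spots and well below saturation, with independent noise on each probe and array. These rates therefore do not cover dim probes or deviations that probes or arrays share. Gene lists were tested with camera of limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 30 lists of at least 5 measured genes, and again with an estimated correlation and with fry. In a simulation over the 5171 genes, camera of limma called 2 of 2 shifted lists of 20 genes and 0 of 18 unshifted lists, of which 0 passed an unadjusted p under 0.05. The simulated genes varied independently of one another, so this could not test whether the preset correlation holds for real lists. The simulated shift was also larger than most of the list medians found here. The main lists were T cells, B cells, neutrophils, macrophages, inflammatory mediators, interferon response, antigen presentation, olfactory sensory neurons, chemoreceptors, neuronal progenitors and cell cycle. The others were complement, cytotoxic and innate lymphoid cells, apoptosis, motile cilia, surface epithelium and mucus, detoxification, stress response, immediate early genes, matrix and fibroblasts, endothelium, erythrocytes, skeletal muscle, pigment cells, bone and cartilage, glia and ensheathing cells, central neurons, eye, ribosomal proteins and oxidative phosphorylation. After the data had been read, 4 genes that matched a list only through an old synonym or a name pattern of another gene were taken out of that list: notch1a from skeletal muscle, tnfrsfa from inflammatory mediators, emc8 from oxidative phosphorylation and ppiaa from detoxification. notch1a stays in the neuronal progenitor list and tnfrsfa in the apoptosis list, as members by their own names.

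The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined, apart from the exceptions stated here and the additions listed with the alternatives. The rule names the 10 genes with the largest rise and the 10 with the largest fall among called probes whose 1 symbol is not a clone, locus or expressed sequence tag identifier and whose 3 mutant arrays all lie on one side of the 3 wild-type arrays. It then names rag1 and rag2, up to 6 genes of each main list by size among those that passed when adjusted over the list alone, and up to 4 genes of each further list by size among those called over all probes. Genes named outside this rule were chosen after their values were seen and are marked so.

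Whether the numbers pair the samples was checked from each array's deviations from its group mean. Arrays with the same number had correlations across probes of 0.317, 0.223 and 0.284, and the pairs with different numbers lay between -0.251 and -0.0676. Deviations from a group mean cancel within the group, so the negative values follow in part from the positive ones. No test was run on these correlations. Same-numbered samples thus deviated together, which comes from the data and not from a statement of the labels, and the fit with the number as a block is given as an alternative. Alternatives covered the background correction, the normalization, the filter, the authors' table, trended and robust eBayes, array weights, the block, leaving out each array in turn, the mean of all probes of a gene, and other set tests. Added after seeing the data were the offset on the summed brightness, the misread block kept, both number 2 arrays left out, probes with unevenly bright spots left out, probes bright on 1 array alone left out, and every current odorant receptor symbol in the chemoreceptor list.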

Results

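Transcript levels were measured in olfactory rosettes of adult zebrafish, in 3 samples from wild-type siblings and 3 from homozygous Rag1 mutants, with 1 array per sample and 15611 probes tested. The median gene spot was 4.84, 5.65 and 7.37 times as bright as the blank spots on wild-type arrays 1 to 3 and 5.21, 5.72 and 5.67 times on mutant arrays 1 to 3. Across probes the arrays had correlations of 0.981 to 0.988 within wild type, 0.983 to 0.987 within the mutants and 0.963 to 0.973 between the groups. No arrays were identical: the SD of the log2 differences between arrays of a group was at least 0.347.

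The gene that carries the mutation, rag1, encodes a subunit of the recombinase that assembles antigen receptor genes. Its probe read 6.48, 6.71 and 6.64 on the log2 scale on wild-type arrays 1 to 3 and 6.68 and 6.74 on mutant arrays 1 and 2, close to the level of the blank spots. Mutant array 3 read 11.92, from a spot with very uneven pixels, whose pixel SD was 3.18 times its mean against 0.151 to 0.195 on the other arrays. The difference between the groups was 1.84 (SE 1.27, n = 3 per group) and did not pass limma's test (adjusted p = 0.483). Without mutant array 3 it was 0.10, and the adjusted p ranged from 0.336 to 0.776 over the alternatives. A transcript this faint in wild type, and a probe whose place relative to the mutation is unknown here, checks no label. rag2, the gene of the other subunit, differed by -0.16 (SE 0.17, limma adjusted p = 0.694).

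The comparison of mutants with siblings asks how the olfactory organ differs in fish that lack the recombinase. Of 11 neutrophil and 16 macrophage genes, 4 and 8 rose in the mutants, among them lysozyme (lyz, 10.4-fold, log2 3.38, SE 0.37, n = 3 per group) and myeloid peroxidase (mpx, 7.85-fold, log2 2.97, SE 0.40). Of 16 interferon response genes 6 rose, and of 50 cell cycle genes 5 did, the replicative helicase genes mcm3 and mcm6 among them. Of 19 chemoreceptor genes, with a median log2 of -0.85, 8 fell, all of them odorant receptors, and the cyclic nucleotide-gated channel gene cnga2 fell by 1.19 (SE 0.16). Camera of limma called these 5 lists with its preset correlation, and each had an adjusted p = 0.192 with an estimated correlation. The T-cell kinase zap70 fell by 2.06 (SE 0.29), and the class I major histocompatibility transcript mhc1ufa fell by 7.46 (SE 0.11) while mhc1uda fell by 7.26 (SE 0.15) at 1 of its probes. The mutant readings of mhc1ufa lay close to the blank spots, so the size of its fall is uncertain.

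Of the 15611 probes, 747 (4.785%) passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 379 higher and 368 lower in the mutants. A change of at least 2-fold was seen in 374 of them, 206 higher and 168 lower. At an unadjusted p under 0.01 there were 1528 probes (735 higher, 793 lower) where chance gives 156.11. The mutant and wild-type arrays did not overlap in 4017 probes (25.7%, where chance gives 10%), and all 747 called probes were among them. Exactly 1 gene symbol was accepted for 272 of the called probes. The other 475 stayed unnamed, as did all probes with no symbol, several symbols or a disagreeing accession. Among them was the probe with the largest fall, spot 9936 (-8.56, SE 0.12, limma adjusted p = 8.68e-08). The count of 747 was 296 without wild-type array 2, 299 without wild-type array 3, and 247, 493 and 298 without mutant arrays 1, 2 and 3. The count of 374 was 244 without wild-type array 2, 249 without wild-type array 3, and 215 and 239 without mutant arrays 1 and 3. Without both number 2 arrays, which leaves 2 per group, 80 probes passed, 75 of them among the 747. There 51 of 71 called named probes lost the call, and it was kept by mhc1ufa, mhc1uda, lyz, mpx, cpa5, lgals9l1, phf11, hp, cahz, ddit4, pkp1b, apom, zc3h7ba, samsn1a, ogfr2, camsap1a, ifi44a5, anxa13l and sppl2. With the number of the sample as a block, since arrays of the same number deviated together, 1117 probes passed. The block ended the calls of neurod4, or42e1, pkp1b and sncb and added those of anln, ccnb1, ccnd1, lgmn, or42c1, or70a4, sypb and tyms.

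**Figure D1:**
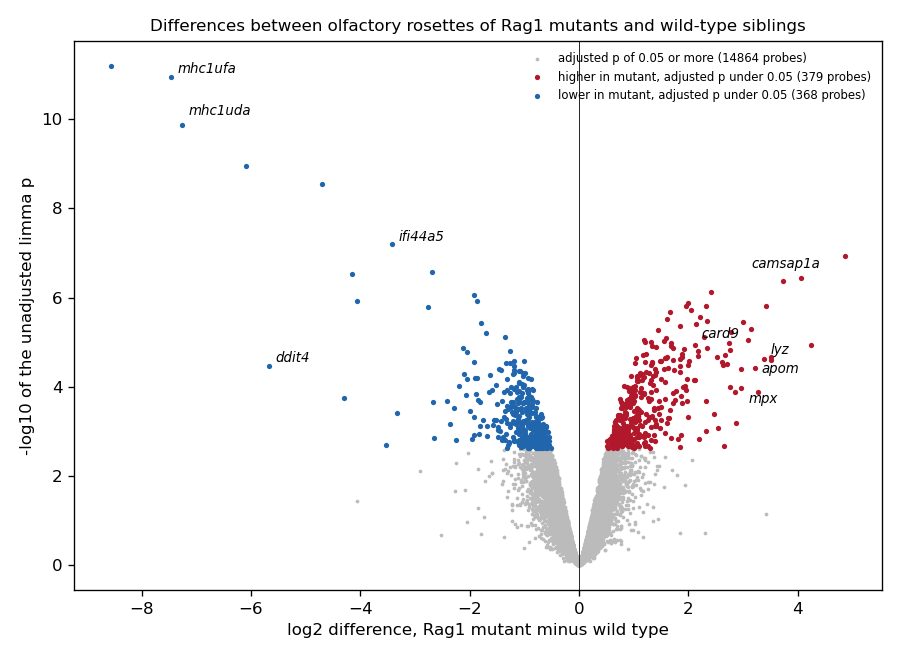
Each point is 1 of the 15611 probes, with the log2 difference between mutant and wild type (3 arrays each) on the x axis and minus log10 of the unadjusted limma p on the y axis. Red and blue points are the 379 higher and 368 lower probes past an adjusted p of 0.05. The class I genes mhc1ufa and mhc1uda lie far to the left, and lyz and mpx to the right.

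Of 16 macrophage genes measured, 8 rose, with a median log2 of 0.86, and 11 rose when adjusted over the list alone. They included the galectin lgals9l1 (2.13, SE 0.18, limma adjusted p = 0.00217), spi1b, which encodes a transcription factor of myeloid development (1.46, SE 0.22, 0.0143), the perforin-like mpeg1.1 (1.19, SE 0.26, 0.0443), the actin-bundling lcp1 (1.05, SE 0.19, 0.0248) and the colony-stimulating factor receptor csf1ra (0.95, SE 0.13, 0.0113). The lysosomal protease gene lgmn was at 0.97 and passed over the list alone. The list as a whole was higher (camera of limma, adjusted p = 2.67e-09), with an adjusted p = 0.192 with an estimated correlation. Of 11 neutrophil genes, 4 rose and 5 did so over the list alone, with a median of 0.61 that was 0.36 without wild-type array 1. Beside lyz (limma adjusted p = 0.00537) and mpx (0.0104), these were the carboxypeptidase cpa5 (2.00, SE 0.23, 0.00579) and alox5ap, needed for leukotriene synthesis (1.39, SE 0.26, 0.0285). Membership in this list was fixed beforehand, and whether cpa5 marks neutrophils rather than other myeloid cells was not tested. The myeloid transcription factor gene cebpa was at 0.90 and passed over the list alone. The neutrophil list was higher (camera adjusted p = 0.000699), with an adjusted p = 0.192 with an estimated correlation. Markers of red blood cells were also higher in the mutants, by a median of 0.19, or 0.30 without wild-type array 2 and 0.33 without mutant array 2 (adjusted p = 0.332 with an estimated correlation). Leaving out 1 array ended the call of spi1b (wild-type 2, wild-type 3 or mutant 3, limma adjusted p up to 0.0564), mpeg1.1 (any array but mutant 2, adjusted p up to 0.13) and lcp1 (any array but wild-type 1 and mutant 2, adjusted p up to 0.086). The same held for csf1ra (mutant 1, limma adjusted p up to 0.0514) and alox5ap (any array but wild-type 1, adjusted p up to 0.095). Over all alternatives limma's adjusted p ranged from 0.00201 to 0.158 for these genes.

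Of 10 inflammatory mediators, 3 rose (5 over the list alone) around a median of 0.61: socs3b, an inhibitor of cytokine signalling (1.39, SE 0.29, limma adjusted p = 0.0414), the haemoglobin-binding acute phase gene hp (1.37, SE 0.27, 0.0355) and the kinase ripk2, which acts downstream of intracellular sensors of bacteria (0.88, SE 0.13, 0.0141). The chemokine genes cxcl14 (0.74, or 0.47 without wild-type array 1) and ccl27a (0.49) passed over the list alone. This list was higher (camera adjusted p = 0.00176), with an adjusted p = 0.332 with an estimated correlation. Of 16 interferon response genes, 6 rose (7 over the list alone) around a median of 0.44. They were ifi27.3 (2.11, SE 0.27, limma adjusted p = 0.00827), the nucleotide kinase cmpk2 (2.01, SE 0.22, 0.00538), phf11 (1.89, SE 0.20, 0.00524), the signalling genes stat2 (1.66, SE 0.29, 0.0229) and irf9 (1.36, SE 0.17, 0.00752), and adar (0.80, SE 0.16, 0.0395), which was named after its value was seen. The transcription factor gene irf1a was at 0.87 (0.57 without both number 2 arrays) and passed over the list alone. The interferon list was higher (camera adjusted p = 2.71e-06), with an adjusted p = 0.192 with an estimated correlation. The red blood cell list, with a median of 0.19 (0.30 without wild-type array 2 and 0.33 without mutant array 2), moved in the same direction as both lists. Calls that ended when 1 array was left out were those of socs3b (any array but wild-type 3, limma adjusted p up to 0.131), hp (any array but mutant 2, adjusted p up to 0.112) and ripk2 (wild-type 2, mutant 1 or mutant 3, adjusted p up to 0.0591). The same held for stat2 (any array but wild-type 1 and mutant 3, limma adjusted p up to 0.0724) and adar (any array but wild-type 1, adjusted p up to 0.127). Across the alternatives limma's adjusted p ranged from 0.00313 to 0.255 for these genes.

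Antigen presentation genes moved both ways. Of 20 measured, 4 rose and 2 fell (9 and 2 over the list alone). Class I genes encode the cell-surface proteins that display peptides to T cells, and mhc1ufa fell from a mean log2 brightness of 13.81 in wild type to 6.35 in the mutants (limma adjusted p = 8.68e-08). That mutant level was close to the lowest readings above the blank spots, 6.13 to 6.19 on the mutant arrays. The size of the mhc1ufa fall is therefore uncertain. A probe of mhc1uda went from 14.20 to 6.94 (adjusted p = 6.92e-07), while its other probe went from 13.59 to 11.90 and fell by 1.69 (SE 0.15, adjusted p = 0.00296). The genes that rose were subunits of the immunoproteasome, which cuts the peptides that class I molecules carry: psmb8a (1.08, SE 0.18, limma adjusted p = 0.0217), psmb9a (1.03, SE 0.15, 0.0125), psmb13a (1.01, SE 0.15, 0.0143) and, named after its value was seen, psmb12 (0.82, SE 0.14, 0.022). The peptide-loading gene tapbp.1 was at 0.89 and passed over the list alone. The list's median was 0.30 and its mean -0.04, and camera placed it higher (adjusted p = 0.00745), with an adjusted p = 0.332 with an estimated correlation. By fry, which sums the genes' own changes, it was lower (limma, adjusted p = 0.0473), and over the alternatives the adjusted p ranged from 1.44e-06 to 0.332. Without 1 of the arrays no call remained for psmb8a (any array but mutant 1, limma adjusted p up to 0.0704), psmb13a (mutant 3, adjusted p up to 0.0509) and psmb12 (any array but wild-type 2, adjusted p up to 0.081). The limma adjusted p over all alternatives ranged from 0.00645 to 0.146 for these genes.

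Genes of T cells were few on the array. Of 9 measured, zap70 (limma adjusted p = 0.0122) and the T-cell receptor constant gene trac (-1.10, SE 0.16, adjusted p = 0.0129) fell. Over the list alone the same 2 genes fell and 2 others were higher, the transcription factor genes runx3 (0.73) and tox (0.56). The list's median was -0.16 and it was not called (camera adjusted p = 0.419). Of 6 B-cell genes, the kinases syk (1.41, SE 0.19, limma adjusted p = 0.0111) and lyn (1.21, SE 0.13, 0.00543) rose, both of which also act in myeloid cells, and both passed over the list alone. The B-cell list had a median of -0.02 but a mean of 0.38 and an upward camera test that did not pass (adjusted p = 0.243). The immunoglobulin light chain constant gene igl1c1, which is in no list, fell by 2.04 (SE 0.26, limma adjusted p = 0.00818). Of 6 genes of cytotoxic and innate lymphoid cells, 2 rose, both from a family of immune-type receptors of fish, nitr4a (1.42, SE 0.26, limma adjusted p = 0.0273) and nitr3a (0.81, SE 0.14, 0.026), and 4 were higher over the list alone. That list had a median of 0.77 (camera adjusted p = 0.00273), with an adjusted p = 0.192 with an estimated correlation. Leaving out 1 array ended the call of trac (wild-type 2, limma adjusted p up to 0.0505), nitr4a (any array but mutant 1 and mutant 2, adjusted p up to 0.08) and nitr3a (any array but wild-type 1, adjusted p up to 0.0942). Over all alternatives limma's adjusted p ranged from 0.00327 to 0.144 for these genes.

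**Figure D2:**
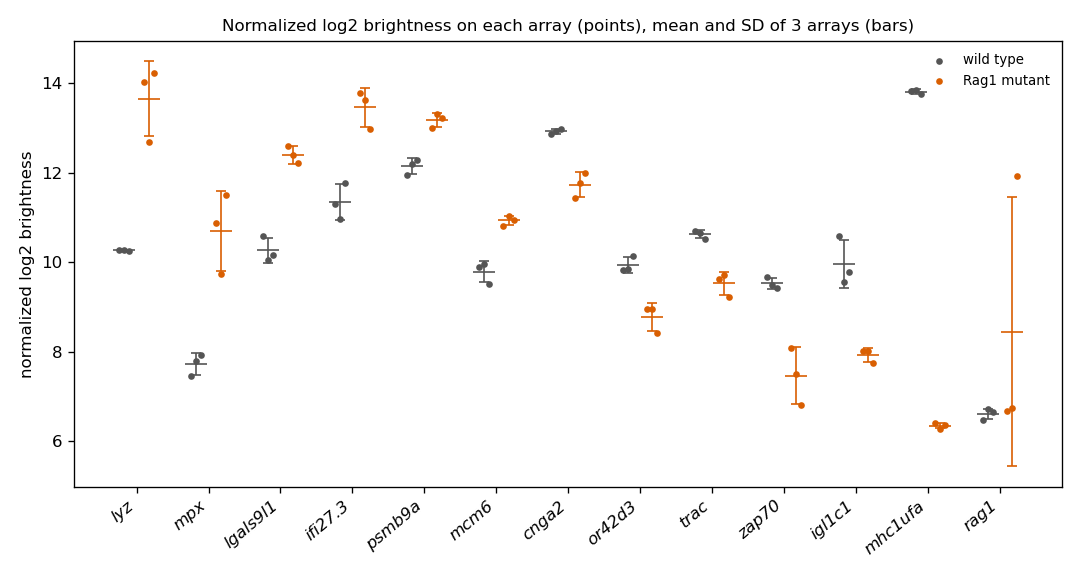
Normalized log2 brightness of genes named in the text on each array (points), with the mean and SD of the 3 wild-type arrays in grey and of the 3 mutant arrays in orange. lyz and mpx are higher on all 3 mutant arrays, mhc1ufa is lower on all of them, and the rag1 difference rests on mutant array 3 alone.

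Of 19 chemoreceptor genes, which encode the receptors of olfactory sensory neurons, 8 fell, and 13 did so over the list alone. Among them were or42d3 (-1.16, SE 0.18, limma adjusted p = 0.0175), or42e1 (-1.09, SE 0.23, 0.0403), or70a2 (-1.07, SE 0.16, 0.0145) and or42c4 (-1.04, SE 0.21, 0.0376). or70a4 (-1.72) and or42c1 (-1.29) passed over the list alone. The chemoreceptor list was lower (camera adjusted p = 3.16e-09), with an adjusted p = 0.192 with an estimated correlation. Of 22 other genes of olfactory sensory neurons, 18 were below 0, with a median of -0.31, and 4 fell (6 over the list alone): the synaptic genes cplx2a (-1.26, SE 0.23, limma adjusted p = 0.0288) and sypa (-1.08, SE 0.20, 0.0293), the channel gene cnga2 (0.0109) and the G protein subunit gene gng13b (-0.69, SE 0.15, 0.0453). sypb (-1.05) and the transcription factor gene ebf2 (-0.43) passed over the list alone. This list too was lower (camera adjusted p = 0.00087), with an adjusted p = 0.192 with an estimated correlation. In the same samples the medians of other cell types that camera called included 0.86 for macrophages, 0.61 for neutrophils (0.36 without wild-type array 1), 0.19 for red blood cells (0.30 without wild-type array 2 and 0.33 without mutant array 2), 0.21 for glia (0.12 without mutant array 1) and -0.26 for motile cilia (-0.16 without wild-type array 1). These lists had an adjusted p of 0.192, 0.192, 0.332, 0.252 and 0.358 with an estimated correlation. Cell types that camera did not call included surface epithelium (-0.02), matrix and fibroblasts (0.04), endothelium (0.08), skeletal muscle (0.07), pigment cells (0.09), bone and cartilage (0.11) and central neurons (-0.03). Calls that ended when 1 array was left out were those of or42d3 (wild-type 2 or wild-type 3, limma adjusted p up to 0.0624), or42e1 (any array but wild-type 2, adjusted p up to 0.121) and or70a2 (wild-type 3 or mutant 3, adjusted p up to 0.0573). The same held for or42c4 (any array but wild-type 1, limma adjusted p up to 0.119), cplx2a (any array but wild-type 1 and mutant 2, adjusted p up to 0.0891) and sypa (any array but wild-type 2 and mutant 2, adjusted p up to 0.0956). It also held for gng13b (any array, limma adjusted p up to 0.138). Across the alternatives limma's adjusted p ranged from 0.00274 to 0.182 for these genes.

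Of 51 genes of neuronal progenitors and young neurons, 2 fell, in the whole comparison and over the list alone: her6, a Notch-responsive repressor of neurogenesis (-1.25, SE 0.17, limma adjusted p = 0.0101), and neurod4, a neurogenic transcription factor gene (-0.56, SE 0.12, 0.0455). The list had a median of -0.03 and was not called (camera adjusted p = 0.296). Of 50 cell cycle genes 47 lay above 0, with a median of 0.48 (camera adjusted p = 1.17e-11, and adjusted p = 0.192 with an estimated correlation). Markers of macrophages (median 0.86) and red blood cells (0.19, or 0.30 without wild-type array 2 and 0.33 without mutant array 2) were higher with them, with an adjusted p = 0.192 and 0.332 with an estimated correlation. Of these 5 rose, and 26 did so over the list alone. The largest were the replicative helicase genes mcm3 (1.27, SE 0.28, limma adjusted p = 0.0474) and mcm6 (1.14, SE 0.15, 0.0104), and gins3, ezh2 and zgc:110540, named after their values were seen, rose by 0.71, 0.61 and 0.75. The cytokinesis gene anln (1.00), the nucleotide synthesis gene tyms (0.95) and the cyclin genes ccnd1 (0.90) and ccnb1 (0.83) passed over the list alone. Of 19 genes of motile cilia, 18 were below 0 with a median of -0.26, which was -0.16 without wild-type array 1 and -0.42 without both number 2 arrays, and 1 fell, in the whole comparison and over the list alone, the central pair gene spag17 (-0.64, SE 0.14, limma adjusted p = 0.0463). The cilia list was lower (camera adjusted p = 0.00176), with an adjusted p = 0.358 with an estimated correlation. Without 1 of the arrays no call remained for neurod4 (any array, limma adjusted p up to 0.134), mcm3 (any array but wild-type 1, adjusted p up to 0.125) and gins3 (any array, adjusted p up to 0.1). The same held for ezh2 (any array, limma adjusted p up to 0.114), zgc:110540 (any array but wild-type 3, adjusted p up to 0.11) and spag17 (any array, adjusted p up to 0.136). The limma adjusted p over all alternatives ranged from 0.011 to 0.254 for these genes.

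**Figure D3:**
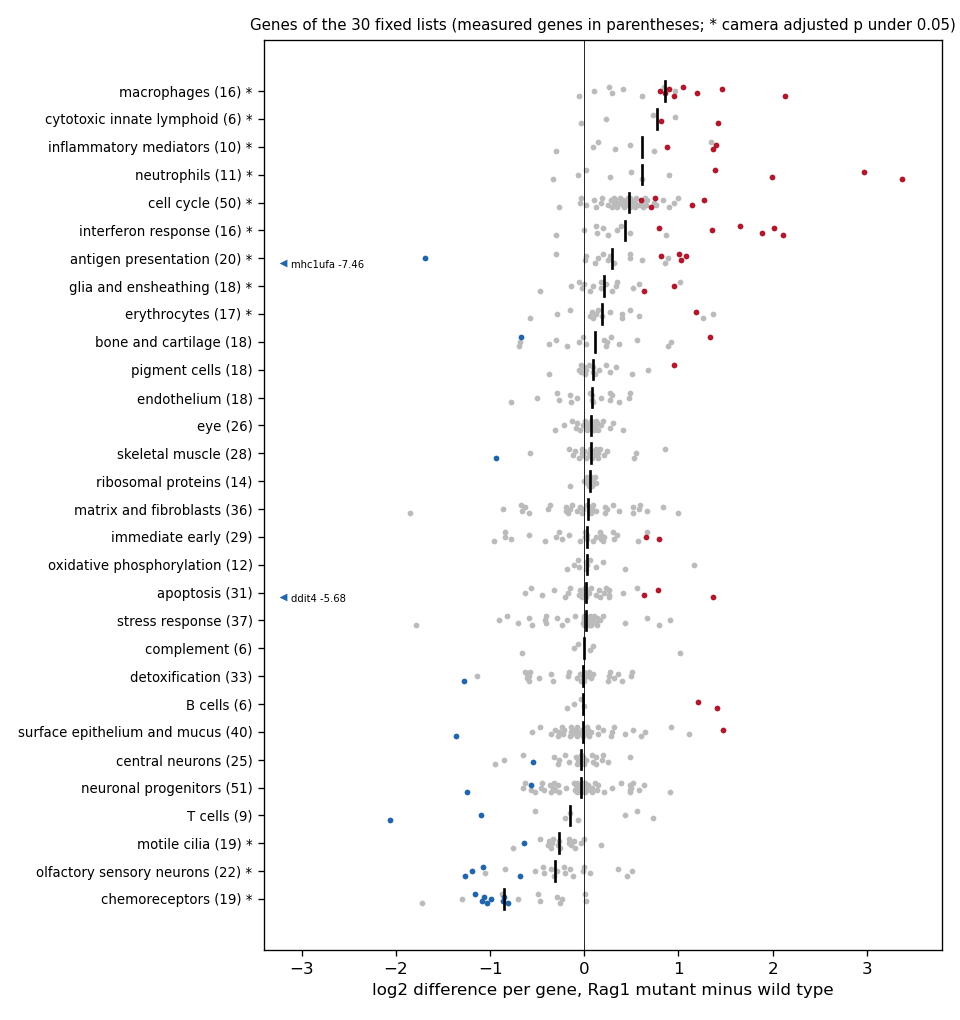
Each point is 1 gene, placed by its log2 difference between mutant and wild type (3 arrays each), in the 30 fixed lists with the number of measured genes in parentheses. Red and blue points passed an adjusted p of 0.05 over all probes, black bars are list medians, and asterisks mark camera's calls with the preset correlation, from macrophages with a median of 0.86 to chemoreceptors with -0.85, which all have an adjusted p of at least 0.192 with an estimated correlation.

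Among the other lists, red blood cell genes were higher with a median of 0.19, or 0.30 without wild-type array 2, 0.33 without mutant array 2 and 0.34 without both (camera adjusted p = 0.00742), with an adjusted p = 0.332 with an estimated correlation. Of 17 measured 1 rose, the carbonic anhydrase gene cahz (1.19, SE 0.24, limma adjusted p = 0.0377), and 7 did so over the list alone. Genes of glia and ensheathing cells, which wrap the olfactory axons, were higher with a median of 0.21 over 18 genes (camera adjusted p = 0.0348), with an adjusted p = 0.252 with an estimated correlation. The tight junction gene cldn11b (0.95, SE 0.12, limma adjusted p = 0.00743) and the secreted Wnt inhibitor gene frzb (0.64, SE 0.12, 0.0343) rose, over the list alone too. The glial median was 0.12 without mutant array 1. The glial call was lost without wild-type array 2, mutant array 1 or mutant array 3 (camera adjusted p = 0.143, 0.0996 and 0.0653, in a range of 0.000846 to 0.252 over the alternatives). Leaving out 1 array ended the call of cahz (any array but mutant 2, limma adjusted p up to 0.119) and frzb (any array but wild-type 1, adjusted p up to 0.116). Over all alternatives limma's adjusted p ranged from 0.00946 to 0.194 for these genes.

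Of 31 apoptosis genes, 3 rose and 1 fell (4 and 3 over the list alone). The inflammatory caspase gene caspb rose by 1.36 (SE 0.18, limma adjusted p = 0.00997) at 1 probe and stood at 0.13 at the other, pdcd6 rose by 0.78 (SE 0.12, 0.0174), cflara, an inhibitor of death receptor signalling, by 0.63 (SE 0.14, 0.047), and the stress-induced inhibitor of mTOR signalling ddit4 fell by 5.68 (SE 0.65, 0.00587). The mutant readings of ddit4, 6.29 to 7.12, came near the blank spots, and its wild-type readings spread from 10.76 to 13.58. The size of the ddit4 fall is therefore uncertain and was -6.65 to -4.85 over the alternatives. The apoptosis list had a median of 0.02, a mean of -0.09 and an upward test that did not pass (camera adjusted p = 0.668). In the surface epithelium and mucus list 1 of 40 genes rose, the galectin gene lgals1l1 (1.48, SE 0.28, limma adjusted p = 0.0293, and 1.63 at its other probe), and 1 fell, the desmosomal pkp1b (-1.36, SE 0.28, 0.04, and -1.11 at its other probe). The median was -0.02, the mean 0.05 and the test upward (camera adjusted p = 0.946), and the same counts held over the list alone. Of 33 detoxification genes 1 fell, over the list alone too, the sulfotransferase gene sult2st1 (-1.28, SE 0.20, limma adjusted p = 0.0168), with a list median of -0.02 (camera adjusted p = 0.185). Calls that ended when 1 array was left out were those of pdcd6 (any array but wild-type 1 and wild-type 3, limma adjusted p up to 0.0687), cflara (any array, adjusted p up to 0.146) and lgals1l1 (any array but wild-type 1 and mutant 2, adjusted p up to 0.102). The same held for pkp1b (any array but wild-type 2, limma adjusted p up to 0.125) and sult2st1 (wild-type 3 or mutant 1, adjusted p up to 0.0587). Across the alternatives limma's adjusted p ranged from 0.0026 to 0.269 for these genes.

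In the immediate early list 2 of 29 genes rose, over the list alone too, ier5l (0.79, SE 0.17, limma adjusted p = 0.0471) and myca (0.66, SE 0.14, 0.0458). Its median was 0.03, its mean -0.02 and its test upward (camera adjusted p = 0.946). Of 18 bone and cartilage genes, the fin-fold actinotrichia gene and1 rose (1.33, SE 0.23, limma adjusted p = 0.022) and the proteoglycan gene spock3 fell (-0.67, SE 0.12, 0.0285), with 1 and 2 genes over the list alone, a median of 0.11 and no call (camera adjusted p = 0.793). Of 28 skeletal muscle genes 1 fell, the glycogen phosphorylase gene pygmb (-0.93, SE 0.20, limma adjusted p = 0.0438), with 1 higher and 1 lower over the list alone and a median of 0.07 (camera adjusted p = 0.477). Of 25 central neuron genes 1 fell, the synuclein gene sncb (-0.55, SE 0.12, limma adjusted p = 0.0474), and 0 passed limma's test over the list alone, where 4 had an unadjusted p under 0.05. The list had a median of -0.03 (camera adjusted p = 0.287). Of 18 pigment cell genes 1 rose, csf1ra, which is also a macrophage gene, and 2 over the list alone, with a median of 0.09 (camera adjusted p = 0.168). Without 1 of the arrays no call remained for ier5l (any array but wild-type 1, limma adjusted p up to 0.14), myca (any array but wild-type 1, adjusted p up to 0.141) and and1 (mutant 2 or mutant 3, adjusted p up to 0.0768). The same held for spock3 (any array but wild-type 1, limma adjusted p up to 0.102), pygmb (any array but wild-type 1, adjusted p up to 0.128) and sncb (any array, adjusted p up to 0.149). The limma adjusted p over all alternatives ranged from 0.0053 to 0.289 for these genes.

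No gene passed limma's test, over all probes or over the list alone, in 7 further lists. An unadjusted p under 0.05 was seen in 2 of 6 complement genes, 7 of 37 stress response genes, 11 of 36 matrix and fibroblast genes, 5 of 18 endothelial genes, 0 of 26 eye genes, 0 of 14 ribosomal protein genes and 1 of 12 genes of oxidative phosphorylation. The medians were -0.00347 for complement (mean 0.05, downward test, camera adjusted p = 0.958), 0.01 for stress response (mean -0.09, downward test, 0.65), 0.04 for matrix and fibroblasts (mean -0.01, upward test, 0.946) and 0.08 for endothelium (camera adjusted p = 0.702). They were 0.07 for the eye (camera adjusted p = 0.501), 0.06 for ribosomal proteins (0.65) and 0.02 for oxidative phosphorylation (0.65). In all, camera called 12 of the 30 lists with its preset correlation and 0 after adjustment with an estimated correlation, where 7 lists passed an unadjusted p under 0.05. fry of limma, which tests a list's own genes without setting them against others, called 11 of the 12, antigen presentation in the opposite direction.

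Among the genes with the largest rise, card9, an adaptor of fungal recognition in myeloid cells (2.12, SE 0.21, limma adjusted p = 0.004), and samsn1a, an adaptor of blood cell signalling (2.18, SE 0.22, 0.00451), rose 4.35-fold and 4.54-fold. The lipocalin gene apom rose by 3.22 (SE 0.37, limma adjusted p = 0.00629), the mitochondrial cristae gene micos13 by 2.77 (SE 0.25, 0.00291), zc3h7ba by 2.52 (SE 0.27, 0.00524) and ogfr2, of the opioid growth factor receptor family, by 2.64 (SE 0.30, 0.00579) and by 2.55 at its other probe. The wild-type readings of apom, 6.34 to 6.43, were close to the blank spots. The size of the apom rise is therefore uncertain and was 2.36 to 4.39 over the alternatives. camsap1a, which binds microtubule ends, rose by 4.06 (SE 0.25, limma adjusted p = 0.000558) at a probe that was not above the blank spots on 1 wild-type array with 3.13 to 5.36 over the alternatives, and its other probe differed by -0.31 without passing the test. Of the genes that fell, ifi44a5, of an interferon-induced family, went from a mean of 9.58 in wild type to a level that was not above the blank spots on 2 of the 3 mutant arrays (limma adjusted p = 0.000163), so the size of its fall is uncertain and was -5.05 to -2.46 over the alternatives. The annexin gene anxa13l fell by 2.76 (SE 0.21, limma adjusted p = 0.0013), the intramembrane protease gene sppl2 fell by 2.68 (SE 0.16, 0.000506), the early endosome gene rab5aa fell by 2.68 (SE 0.40, 0.0145) and the vitamin E transfer gene ttpa fell by 1.58 (SE 0.22, 0.0111). Leaving out 1 array ended the call of rab5aa (wild-type 3 or mutant 3, limma adjusted p up to 0.057). Over all alternatives limma's adjusted p ranged from 0.00074 to 0.124 for rab5aa.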

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

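The tests of explanations in this part were chosen after the result they bear on had been seen, and only the count over other splits of the arrays was set beforehand. Of the spots with bacterial names, which should find no zebrafish transcript and are used in no comparison, 149 of 216 over the 6 arrays (69%) were brighter than the 95th percentile of the blank spots, with array medians of 1.072 to 1.089 times the blank median.

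The split of the 6 arrays into mutant and wild type gave 747 probes past limma's adjusted threshold, and 1 of the 10 splits into 3 and 3, the real one, gave as many. The highest of the other splits gave 0 by limma, with 988 probes at an unadjusted p under 0.05 against 3285 in the real split, and 10 splits are too few for a share under 0.05.

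The class I genes mhc1ufa and mhc1uda moved most among the lower genes with a name: mhc1ufa fell by 7.46, and 1 probe of mhc1uda fell by 7.26 while its other fell by 1.69. In the mutants mhc1ufa read close to the blank spots, which leaves the size of its fall uncertain. A general loss of antigen presentation transcripts is argued against by the other 18 measured genes of that list, of which 17 were above 0. Their median change was 0.402 (bootstrap interval over genes 0.172 to 0.838). That interval does not measure the spread between samples, and the whole list had a camera adjusted p = 0.332 by limma with an estimated correlation. A loss of lymphocytes stays open. The fall exceeded the largest of trac, zap70 and igl1c1 by 5.2 (SE 0.332). These read 9.53, 7.46 and 7.93 in the mutants, where the lowest readings above the blank spots were 6.13 to 6.19. The blank level thus did not stop their falls, but the nonspecific signal of their probes was not measured. Their wild-type levels left them room to fall by 3.37 to 4.48 only, less than these class I probes fell. A condition on this room was added after the result was known and changed the reading from argued against to open. Set by the wild-type levels, that condition could not be met here, so no conclusion is drawn from this test. A difference in class I haplotype between the fish, with sequences that these probes match in the wild-type fish alone, may account for the fall and stays open: of the 50 measured genes nearest to the class I gene mhc1uba in the gene order of assembly GRCz12tu, proteasome genes left out, 2 were called (4%, with an upper bound of 13.7%, against 4.83% elsewhere, 1-sided Fisher exact p = 0.703), and with the 4 proteasome genes kept, as the test was first run before it was redefined on seeing that result, 6 of 50 were (1-sided Fisher exact p = 0.0343). Neither mhc1ufa nor mhc1uda is among the genes of that table used here, so their own neighbours were not searched, and the rag1 genotype itself stays open and untested.

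The neutrophil and macrophage lists were higher in the mutants, with a median of 0.852 over 27 genes, of which 12 rose, and each list had a camera adjusted p = 0.192 by limma with an estimated correlation. A lower share of sensory neurons would raise all other cell types alike. It is argued against as the whole cause by 138 genes of 5 non-neuronal lists: surface epithelium, endothelium, matrix, skeletal muscle and bone. Their median of 0.0436 lay 0.808 lower (permutation p = 1e-05 over genes, the smallest that 100000 permutations can give). Without each array in turn it lay 0.725 to 0.843 lower (permutation p = 1e-05 each time). These permutations shuffle genes and do not measure the spread between samples. The lists of glia and red blood cells, called higher by camera with medians of 0.21 and 0.19, were not among the 5. More blood in the mutant samples stays open: the median of 17 red blood cell genes, 0.193, lay 0.659 lower (permutation p = 0.00894), but 0.481 lower without wild-type array 2 and 0.494 lower without mutant array 2 (permutation p = 0.0852 and 0.0932), a condition that was added after the first p was known and that changed the reading from argued against to open, and genes are not independent replicates. More myeloid cells in the mutant rosettes, or more transcript per cell, are hypotheses that remain and that these arrays cannot separate.

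On mutant array 3 the rag1 spot lay 5.18 (log2) above the second highest array. Wild-type tissue in that sample is argued against by the wild-type arrays themselves, which read rag1 at only 6.48 to 6.71. The same explanation is also argued against by trac, zap70, igl1c1, mhc1ufa and ifi44a5. Their mean position on that array between the other mutant arrays at 0 and the wild-type arrays at 1 was -0.24 (SD 0.264). Many spots bright on that array alone were not found. It had 1 other probe at least 8-fold above the second highest array, where at least 5 were the condition, set after the rag1 reading was seen. Each of the other arrays had 0 such probes, so mutant array 3 still stood apart. A flaw within that spot may be the source: its pixel SD over its mean was 3.18, at percentile 100 of 1156 spots of similar brightness, whose median was 0.307 and whose highest was 1.02, in a test added after the count of other bright spots had come out low. Transcription of rag1 in that sample was not tested.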

How the results depend on the processing

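Of the settings, the misread block kept, the offset on the summed brightness, both number 2 arrays left out, probes with unevenly bright spots or bright on 1 array alone left out, and every current odorant receptor symbol were chosen after the data had been seen. The 88 named probes kept their sign in every setting that tested them, and each setting of background, scaling, filter, value source, fit or probe choice called 12 lists. The count of called probes, 747, was 601 with no background correction, 638 with plain subtraction, 944 with median scaling, 919 with 75th percentile scaling, 810 with cyclic loess, 744 with no filter, 734 with probes above the blank spots on all 6 arrays, 947 from the authors' table, 944 with trended and robust eBayes, 1020 with array weights, 735 with the offset on the summed brightness, and 747 both without unevenly bright spots (746 shared) and without spots bright on 1 array alone. With the misread block kept it was 604, of which 600 were shared. With no background correction 244 probes passed with at least 2-fold change against 374, and the cause was not tested. With the replicate number as a block 1117 probes were called, 696 of them shared, and of the 88 named probes 4 lost the call (neurod4, or42e1, pkp1b and sncb) and 8 gained it (anln, ccnb1, ccnd1, lgmn, or42c1, or70a4, sypb and tyms). Leaving out each array in turn, which leaves fewer samples, gave 247 to 598 called probes (598, 296 and 299 without wild-type arrays 1 to 3 and 247, 493 and 298 without mutant arrays 1 to 3), 215 to 406 with at least 2-fold change, and a glial median of 0.12 to 0.29, not called without wild-type array 2, mutant array 1 or mutant array 3 (camera of limma, adjusted p = 0.143, 0.0996 and 0.0653, within 0.000846 to 0.252 over all alternatives). Of 71 called named probes, 33 kept the call without each array in turn and 38 lost it without at least 1. Without both number 2 arrays 80 probes were called (75 shared), 51 of the 71 named calls ended, 880 had an unadjusted p under 0.01, 80 passed with at least 2-fold change, and detoxification was called with a median of -0.090 (camera of limma, adjusted p = 0.0393, within 0.000651 to 0.825 over all alternatives). Camera of limma with an estimated correlation called 0 lists (7 at an unadjusted p under 0.05) at the same medians: 0.61 for neutrophils, 0.86 for macrophages, 0.61 for inflammatory mediators, 0.44 for interferon response, 0.30 for antigen presentation, -0.31 for olfactory sensory neurons, -0.85 for chemoreceptors, 0.48 for cell cycle, 0.77 for cytotoxic and innate lymphoid cells, -0.26 for motile cilia, 0.19 for erythrocytes and 0.21 for glia. Directional fry also called B cells (median -0.016), skeletal muscle (0.070), pigment cells (0.092) and eye (0.073), did not call motile cilia (-0.26), and placed antigen presentation (0.30) lower. Mixed fry, which asks for change in either direction, called 26 lists, adding T cells (-0.16), B cells (-0.016), neuronal progenitors (-0.034), complement (-0.0035), apoptosis (0.020), surface epithelium (-0.018), detoxification (-0.015), immediate early genes (0.031), matrix (0.043), endothelium (0.080), skeletal muscle (0.070), pigment cells (0.092), bone and cartilage (0.11) and central neurons (-0.033). For both tests the cause was not tested. Gene spots had a median brightness of 4.84 to 7.37 times the blank spots, and the wild-type readings of rag1, close to the blank spots, left little room for a fall. Keeping spots marked by the scanner software and a slide or scan batch as a block were not run, since the files used here give neither.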

Other observations

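The symbol families and genes of the first 2 paragraphs, and their tests, were chosen after the values had been seen, while the tests of gene order were set beforehand. Of 68 families of at least 8 genes that share the letters at the start of a symbol, camera of limma called 2 with its preset correlation. Odorant receptors (23 genes, 9 fell) had a median of -0.81 (adjusted p = 1.98e-10), and beta subunits of the proteasome (9 genes, 4 rose and 1 fell) a median of 0.55 (adjusted p = 0.00526). Both had an adjusted p = 0.83 with an estimated correlation. Both also overlap with lists tested above and are no separate evidence. Odorant receptors are in the chemoreceptor list, and the 4 proteasome genes that rose are in the antigen presentation list. With the preset correlation both kept their direction and call in all 22 other settings, the scalings and each array left out among them, with an adjusted p of up to 2.86e-08 and 0.0349, though the proteasome median was 0.34 without wild-type array 1. The proteasome subunits that rose were psmb8a (1.08), psmb9a (1.03), psmb13a (1.01) and psmb12 (0.82). The gene psmb7, which encodes a subunit of the constitutive proteasome, fell by 0.80 (SE 0.14, n = 3 per group, limma adjusted p = 0.026). It was not called without wild-type array 2, wild-type array 3, mutant array 1 or mutant array 3 (limma adjusted p up to 0.0894, and 0.0156 to 0.141 over all alternatives). Other constitutive subunits were at 0.55 for psmb5, 0.46 for psmb3, 0.36 for psmb6 and 0.20 for psmb4, and these did not pass limma's test (adjusted p = 0.177, 0.152, 0.277 and 0.441).

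Of 228 called genes with a name, 160 were in none of the fixed lists, 83 higher and 77 lower. Higher in every setting, and called without each array in turn, were the interferon-induced ifi44a3 (1.63, SE 0.19, n = 3 per group, limma adjusted p = 0.00629), tspan36 (1.55, SE 0.18, 0.00638), rasgrp4, a signalling gene of blood cells (1.23, SE 0.15, 0.00683), and the decoy receptor gene tnfrsf11b (1.16, SE 0.14, 0.00702). Without both number 2 arrays tspan36 alone of these 4 was called. Others rose but lost the call without at least 1 array. They were the prolactin receptor gene prlra (2.00, SE 0.34, limma adjusted p = 0.0224, lost without wild-type array 1, wild-type array 3 or mutant array 1) and epgn, which encodes a ligand of the epidermal growth factor receptor (1.34, SE 0.23, 0.022, lost without wild-type array 3, mutant array 1 or mutant array 3). Their highest adjusted p without an array was 0.0802 and 0.0742 by limma, within 0.00231 to 0.0802 and 0.00354 to 0.0965 over all alternatives. Among genes that fell were anos1a (-0.74, SE 0.13, limma adjusted p = 0.0239) and anos1b (-0.90, SE 0.19, 0.0405), whose human counterpart is mutated in Kallmann syndrome, in which the sense of smell is lost. The call of anos1a ended without any array but wild-type 1 and that of anos1b without any array but wild-type 2 (limma adjusted p up to 0.0784 and 0.116, within 0.0185 to 0.178 and 0.0112 to 0.116 over all alternatives). The pentraxin gene ptx3a fell by 1.52 (SE 0.27, limma adjusted p = 0.0239) and lost the call without any array but wild-type 3 (up to 0.0777, within 0.00431 to 0.13 over all alternatives).

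Variants linked to the rag1 mutation could alter signals of genes near it. Of the 50 measured genes nearest to rag1 in the gene order of assembly GRCz12tu, 2 were called, gins3 (0.71) and prnprs3 (-0.71), or 4% (upper bound 13.7%) against 4.92% elsewhere. Both lost the call when an array was left out, gins3 with any array and prnprs3 with any but wild-type 1 (limma adjusted p up to 0.1 and 0.147, within 0.0264 to 0.13 and 0.0245 to 0.281 over all alternatives). The 1-sided Fisher exact p was 0.713, and with so few genes linked variants stay open. Variants along the whole genome could place called genes beside one another. Among 5112 measured genes with a place in that order, 12 pairs of neighbours were both called where permuted calls gave 11.9 (permutation p = 0.538), which leaves this open too.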
